A study of Mus musculus with 2 samples.

How the data were processed

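Gene expression was measured in gastrocnemius muscle of female mice aged 10 weeks. Per the labels, 1 sample came from a Pdgfra-CreER:R26-DTA mouse, here called depleted, and 1 from a wild-type R26-DTA littermate, here called control. In the depleted genotype the Cre recombinase, which tamoxifen activates, is made where the Pdgfra promoter is active and switches on diphtheria toxin A from the Rosa26 locus, which kills the cell. Per the labels' protocols, both mice received tamoxifen from 9 weeks of age for 5 days, and the muscle was frozen 2 days after the last dose. RNA was extracted with a column kit, amplified to amino allyl RNA and coupled to Cy5, per the labels' protocols.

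The deposited scanner values are spot intensities: the median pixel of each spot at 635 nm on a linear scale, joined from 3 scan gains, with no background subtraction or normalization, per the file headers. Each array held 27456 spots, of which 2736 were blank, 1102 carried no probe, 96 were negative and 48 positive control spots, and 23473 probes remained. The scanner and its software are not given in the sources used here. All spots carried the scanner's OK flags. The authors also deposited a table of processed intensity values, whose median is 25 on both arrays. Set against the scanner values, it is a straight line on each array: the spot's intensity minus about the mean of the blank spots, multiplied by 1.27 on the control array and by 0.939 on the depleted array. Each array thus has its own factor, which fixes the table's scale and direction, and spots near the blanks are left empty. The column of local background follows the spot's own signal (Spearman correlation across spots 0.942 on the control array and 0.969 on the depleted array), so it was not subtracted in the main setting.

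In the main setting, the spot intensities were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, set on a log2 scale and quantile-normalized over the probes. Spots of a probe were averaged. A gene with several probes was represented by its brightest probe, which concerned 1283 of 19321 genes. A probe counted as above background where its spot exceeded the mean of the blank spots by more than 2 SD. This limit was 37.4 on the control array and 38.5 on the depleted array, against a median probe of 53.3 and 59.8. On the control array 92.6% of probes were above background, and on the depleted array 92.8%. The 18498 genes above background on at least 1 array were compared, and where an array was below background its value was set to the higher of its own and the lowest value above background. The offset draws the ratios of dim genes toward 0, so the authors' deposited values are given beside many ratios. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

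Gene names came from the platform's annotation of the probes, in which 20690 probes have 1 gene symbol, 0 have several and 2783 have none. By Entrez gene, 20556 probes were matched to a current RefSeq table, which changed 0 symbols. No genome build is given in the sources used here, and no positions are printed. Probes of the globin genes can share signal with near-identical copies, so the level of each globin gene is uncertain.

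With 1 array per group there is no replicate check, no spread between animals and no p-value, and the number of arrays limits the precision of every value. Array and group cannot be told apart. By its label the control carried no Pdgfra-CreER, so the presence of CreER and depletion cannot be told apart either. Genes were counted at a 2-fold difference. The ratio of a gene was placed by percentile among the 500 genes closest in mean intensity. The median log2 ratio of a gene list was placed among the medians of 10000 random lists of the same size matched on mean intensity in 20 bins, and a list was said to stand apart when it lay outside the central 95% of them. Such places describe these 2 arrays and are not tests of the genotype. The 33 gene lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Pdgfra, the 15 genes with the highest and the 15 with the lowest ratio among genes above background on both arrays and at or above the median intensity on the brighter array, up to 4 members of a list that stood apart and up to 2 of any other list, taken by size of the ratio, and the 5 brightest genes above background on only the control or only the depleted array. Predicted genes and RIKEN clones were counted but not named, which concerned 1 gene at each end.

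The alternatives were an offset of 16, no background correction, subtraction of the blank spots, scaling to the median, cyclic loess, the authors' processed values, 3 other filters on dim genes, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, lists without members shared with another list, and random lists not matched on intensity. Subtraction of the local background column was added after the data had been seen.

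The steps were tested on simulated data. In a simulated depleted against control pair of arrays with a noise SD of 0.15 on the log2 scale, a value chosen for the simulation, 200 genes were changed. Over 17876 genes above background, 7.00% of those changed 2-fold and 34.7% of those changed 4-fold were counted at the 2-fold threshold, and 0 unchanged genes were. Over the 8938 genes at or above the median intensity, 14.6% of those changed 2-fold and 70.8% of those changed 4-fold were counted. Counts at 2-fold were low in this simulation, also over the brighter genes, and lower still when dim genes were included. Among the brighter genes, those changed 2-fold had a median log2 ratio of 0.65. Genes changed exactly 2-fold lie at the threshold, so part of their low counts comes from the design. On the real arrays, the central 95% of the 4625 brightest genes ran from -0.81 to 0.85, and 3.16% of them differed at least 2-fold. The noise SD was chosen, so the 0 does not show how many unchanged genes were counted on the real arrays. Of 100 unchanged lists of 15 genes drawn from the 18498 genes with their ratios shuffled, 4 stood apart. Of 100 such lists shifted by 0.5 on the log2 scale, 100 did. Shuffling makes genes vary independently, so the first count does not cover lists whose genes move together. The shift was added to normalized ratios, and smaller shifts of lists were not simulated.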

Results

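Expression of 18498 genes was compared between the gastrocnemius, a calf muscle, of 1 Pdgfra-CreER:R26-DTA mouse, labelled as depleted of PDGFRα-positive mesenchymal progenitors and called depleted here, and that of 1 control littermate. These progenitors are interstitial cells that make matrix and can give rise to fat and fibrous tissue. The study asked which genes differ in expression after depletion of these cells. Cell numbers were not analysed here. Each group held 1 array, so all values below are without replicates and every difference may also be one between 2 animals. Log2 ratios are depleted over control throughout, and "deposited values" are the authors' processed intensities.

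Mesenchymal progenitor markers and interstitial matrix genes were lower on the array of depleted muscle. Muscle atrophy genes, macrophage markers and interferon response genes were higher. Erythroid markers were lower too, with the largest median of any list (-2.30), which rests on 4 globin genes. Immediate early genes were higher (0.67). No cause was tested for these last 2 lists. Pdgfra, which marks the targeted cells (probe M200001112), was 1.91-fold lower, with a log2 ratio of -0.94. This lay at percentile 2.40 of the 500 genes closest in intensity, whose central 95% ran from -0.80 to 0.67. Its deposited values were 273.1 in control and 116.6 in depleted muscle. Subtraction of the local background column put Pdgfra at -0.70, inside the range of its neighbours.

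At least 2-fold differences were found for 79 genes that were lower and 91 that were higher in depleted muscle, so 53.5% of these genes were higher. Scaling to the median gave 38 lower and 209 higher genes, or 84.6% higher, and the authors' processed values gave 410 and 604. Both arrays measured 17563 genes above background.

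**Figure D1:**
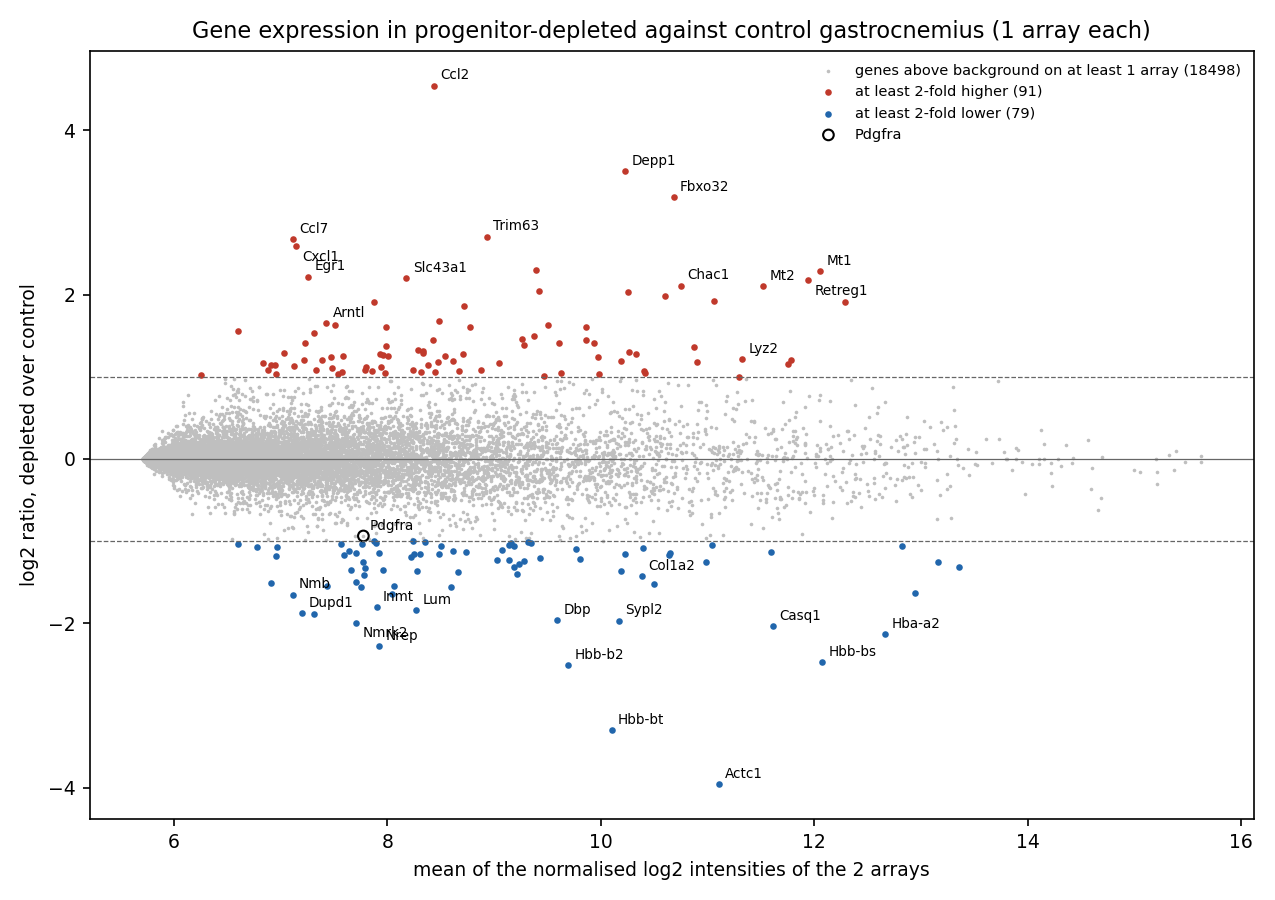
Log2 ratio of depleted over control muscle for each of the 18498 genes against the mean of its normalised log2 intensities on the 2 arrays, with the 91 genes at least 2-fold higher in red, the 79 at least 2-fold lower in blue and dashed lines at 2-fold. Ratios spread more widely among brighter genes, with Ccl2 at 4.54 and Actc1 at -3.96 at the ends and Pdgfra, circled, at -0.94.

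Among the genes with the lowest ratios, Actc1, the cardiac alpha-actin, was 15.5-fold lower, with deposited values of 9854.9 in control and 558.7 in depleted muscle. The beta-globin genes Hbb-bt, Hbb-b2 and Hbb-bs were at -3.30, -2.51 and -2.47 and the alpha-globin gene Hba-a2 at -2.13. Nrep was at -2.28. Casq1, the calcium-binding protein of the fast fibre's sarcoplasmic reticulum, was at -2.03, and Sypl2, a protein of the triad junction, at -1.97. Nmrk2, a nicotinamide riboside kinase of muscle, was at -1.99, the clock output gene Dbp at -1.96, Dupd1 at -1.88, Lum at -1.84, Inmt at -1.80, Nmb at -1.65 and Plcd4 at -1.65. The dimmer probe of Plcd4 gave -0.07, and Inmt was at 0.66 with the local background column subtracted.

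In the main setting the highest ratio belonged to Ccl2, a chemokine that draws monocytes, which was 23.3-fold higher with deposited values of 21.8 in control and 1822.4 in depleted muscle. Depp1, a target of FoxO factors, was 11.4-fold higher, and the ubiquitin ligases Fbxo32 and Trim63, which mark muscle atrophy, were 9.13-fold and 6.53-fold higher. The chemokines Ccl7 and Cxcl1 were at 2.68 and 2.59. Both were dim in control muscle, and in deposited values Ccl7 was 94.3-fold higher (3.5 to 330.2), Ccl2 83.6-fold and Cxcl1 51.4-fold (6.3 to 323.9). The metallothioneins Mt1 and Mt2 were at 2.28 and 2.10, and the immediate early gene Egr1 at 2.22. Slc43a1, an amino acid transporter, was at 2.20, the reticulophagy receptor Retreg1 at 2.17, the glutathione-degrading enzyme Chac1 at 2.11, Cyren at 2.05, Pdk4, which restrains pyruvate oxidation, at 2.03 and Retnla at 1.99. The dimmer probe of Cyren gave -0.17, and Slc43a1 was at -0.27 with the local background column subtracted.

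Mesenchymal progenitor markers were lower as a group. Of 30 measured members 28 were lower, 6 of them at least 2-fold, and the median of -0.53 lay below all 10000 matched random lists (central 95% from -0.09 to 0.08). The members with the largest differences were Lum (-1.84), Dpt (-1.23), Abca8a (-1.19) and Smoc2 (-1.16). Interstitial collagen and matrix genes had a median of -0.30, also below all random lists, with 23 of 28 lower. The fibrillar collagens Col1a2, Col3a1 and Col1a1 were at -1.42, -1.22 and -0.97, and Col6a2 was at -1.06. The dimmer probe of Col3a1 gave -0.42. Basement membrane genes, which several cell types make, had a median of 0.00 at percentile 63.7, with Nid1 at -0.76 and Nid2 at -0.33.

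Signals secreted by mesenchymal cells had a median of -0.08 at percentile 0.36, with 17 of 20 lower. The growth factor binding protein Igfbp5 was at -0.94, the BMP family ligand Gdf10 at -0.66, the cytokine Il33 at -0.63 and Vegfa at -0.61. In deposited values Gdf10 was 3.99-fold lower, from 53.9 to 13.5, and Il33 was 2.71-fold lower. Stromal complement genes had a median of -0.18 at percentile 5.09, within the range of random lists, with Serping1 at -0.55 and Cfb at 0.44. Tenocyte markers had a median of -0.14 at percentile 1.15, with 9 of 12 lower, and were led by Kera (-1.41) and Tnmd (-0.98), followed by Chad (-0.35) and Comp (-0.32). The authors' processed values gave medians of -0.30 for both the secreted signals and the tenocyte markers. With the local background column subtracted, the secreted signals (-0.02) and tenocyte markers (-0.01) lay within the range of random lists and Vegfa was at 0.06.

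Markers of most other resident cell types did not stand apart from random lists. Endothelial markers had a median of 0.03 at percentile 78.6, with Cldn5 at 0.83 and Aqp1 at -0.71, and mural cell markers a median of 0.03 at percentile 84.2, with Tagln at 0.68 and Acta2 at 0.61. Schwann cell markers were at 0.02 (percentile 83.3; S100b -0.29, Egr2 0.23) and adipocyte markers at 0.04 (percentile 84.2; Scd1 -0.80, Cidec -0.32). Muscle stem cell markers had a median of 0.07 at percentile 98.2, just above the random range, with 12 of 14 higher. Cdh15 was at 0.58, Sdc4 at 0.44, Chodl at 0.15 and Hey1 at -0.28. The stem cell list lay within the random range in the authors' processed values (0.21) and under 3 other alternatives, and subtraction of the local background column put its median at -0.01 and Cldn5 at -0.05. Erythroid markers, the globin genes with the other measured members, were all lower, with a median of -2.30 over 6 genes, below all random lists. The 4 members that were at least 2-fold lower were the globin genes named above. Their probes can share signal, so they are not independent measurements, and the median rests on them.

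**Figure D2:**
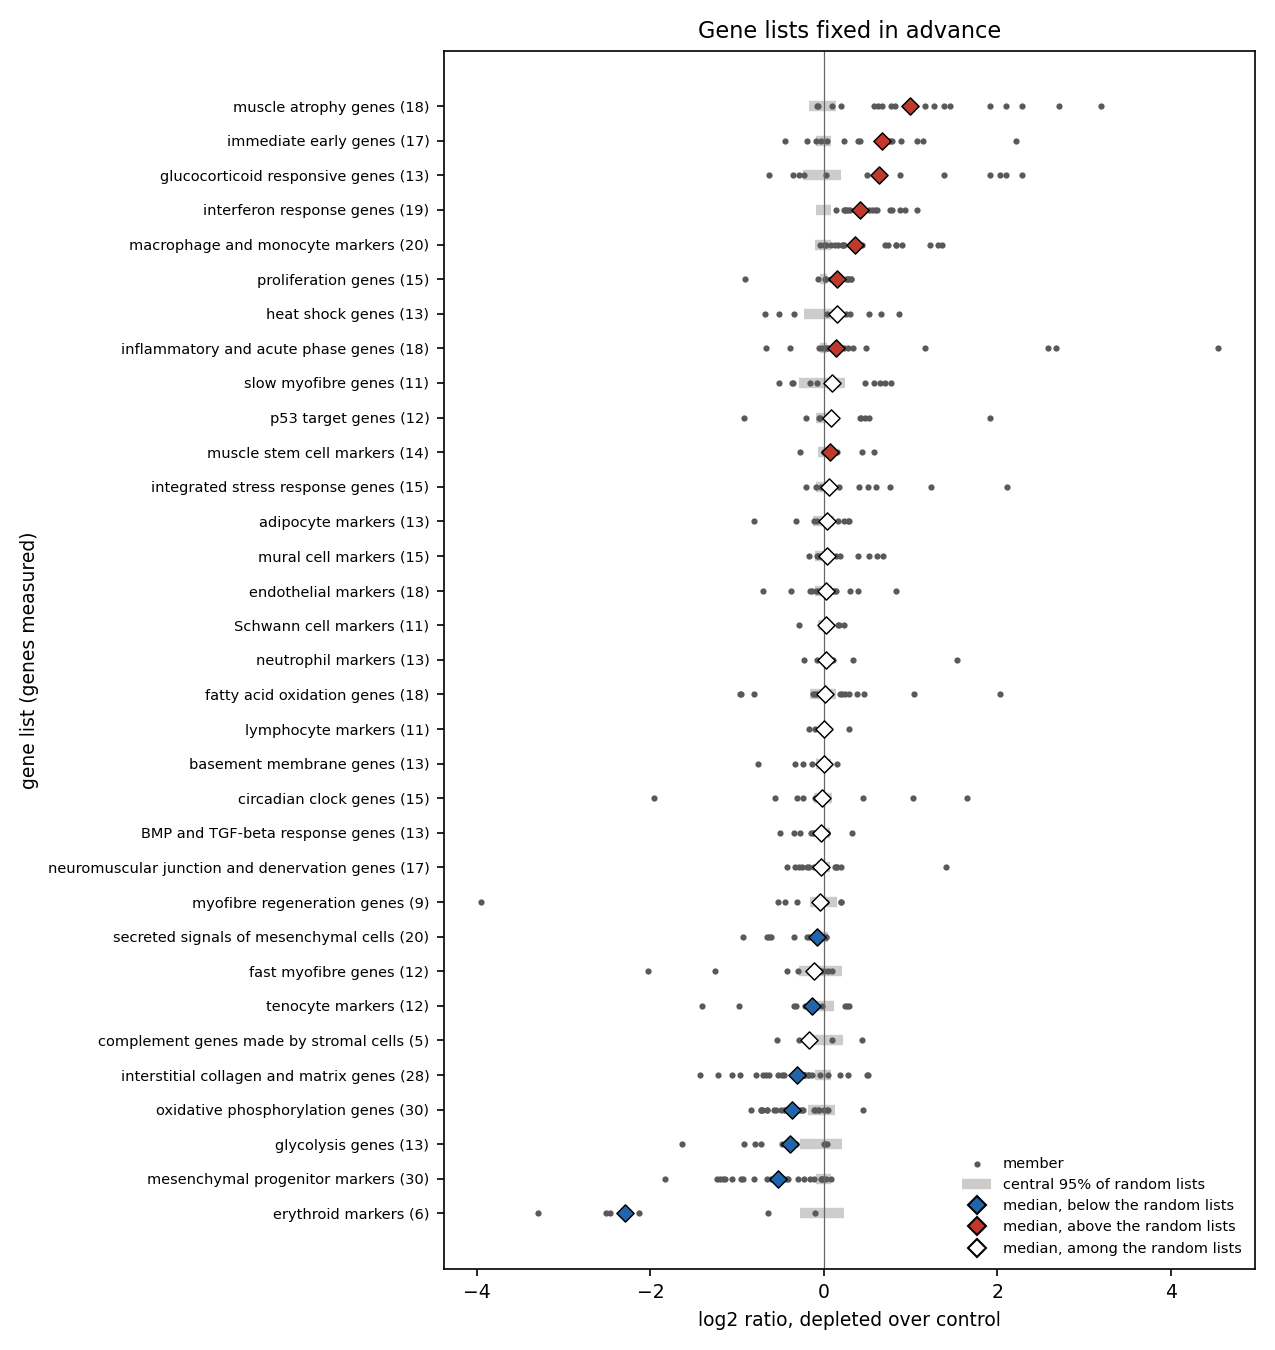
Log2 ratios of depleted over control muscle for the members (points) of each of the 33 gene lists, with the list's median (diamond) and the central 95% of 10000 random lists matched on intensity (grey bar), and the number of genes measured in parentheses. The medians of 7 lists lie below their bars, with erythroid markers at -2.30 and mesenchymal progenitor markers at -0.53, and those of 8 lie above, with muscle atrophy genes at 0.99.

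Macrophage and monocyte markers were higher in depleted muscle in 19 of 20 members, with a median of 0.36 above all random lists. The lysozymes Lyz1 and Lyz2 were at 1.37 and 1.22, the galectin Lgals3 at 1.32 and the complement component C1qc at 0.91. Neutrophil markers had a median of 0.02 at percentile 95.3, with Lcn2 at 1.54 and S100a8 at 0.34, and lymphocyte markers a median of 0.00 at percentile 66.3, with Cd2 at 0.29 and Cd4 at -0.17. Lyz2 was at -2.64 with the local background column subtracted.

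Interferon response genes were higher in 19 of 19 members, with a median of 0.42 above all random lists. Psmb8, a subunit of the immunoproteasome, was at 1.07, and the antiviral genes Ifit1 and Ifit3 and the regulator Usp18 were at 0.93, 0.88 and 0.79. Inflammatory and acute phase genes had a median of 0.14, above all random lists, with 14 of 18 higher and the chemokines Ccl2, Ccl7, Cxcl1 and Ccl8 at 4.54, 2.68, 2.59 and 1.17. In the authors' processed values the medians were larger, at 0.89 for macrophage markers, 0.87 for interferon response genes and 1.07 for inflammatory genes. Subtraction of the local background put the inflammatory list at 0.03, inside the random range, and Ifit3 at -0.08.

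Muscle atrophy genes were higher as a group. Of 18 members 16 were higher, 9 of them at least 2-fold, and the median was 0.99, above all random lists (central 95% from -0.17 to 0.14). Fbxo32 and Trim63 were at 3.19 and 2.71, and Mt1 and Mt2 at 2.28 and 2.10. The 4 members shared with other lists left out, the median was 0.72. Glucocorticoid responsive genes had a median of 0.63, with 9 of 13 higher, also above all random lists. This list shared 6 members with other lists, and Mt1, Mt2, Pdk4 and the cell cycle inhibitor Cdkn1a (1.91) were its largest. Without shared members its median was -0.23, inside the random range. Immediate early genes, which respond to stimuli within minutes, were higher in 13 of 17 members with a median of 0.67, above all random lists. Egr1 was at 2.22, Fos at 1.15, Maff at 1.08 and Btg2 at 0.89. Fos was at -0.10 and Maff at -0.19 once the local background column was subtracted.

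Genes of the neuromuscular junction and of denervation did not stand apart, with a median of -0.04 at percentile 19.5. Gadd45a was at 1.41, while Chrne, the adult subunit of the acetylcholine receptor, was at -0.43. Myofibre regeneration genes had a median of -0.05 at percentile 26.5, with Actc1 at -3.96 and Myod1 at -0.53. Fast myofibre genes had a median of -0.12 at percentile 22.5, with Casq1 at -2.03 and Pvalb at -1.25, and slow myofibre genes a median of 0.10 at percentile 83.2, with Myoz2 at 0.78 and Tnnt1 at 0.71. In the authors' processed values the regeneration (-0.31) and fast fibre (-0.46) medians lay below the random range. Pvalb was at 3.50 and Myoz2 at -3.00 once the local background column was subtracted.

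Oxidative phosphorylation genes were lower in 26 of 30 members, with a median of -0.37 below all random lists (central 95% from -0.19 to 0.13). Differences were small per gene: 0 members lay below the central 95% of genes of like intensity. Cyc1 of complex III was at -0.84, Cox7a1 of complex IV at -0.73, and Ndufs1 and Ndufs8 of complex I at -0.72 and -0.72. Glycolysis genes had a median of -0.39 at percentile 0.27, with 11 of 13 lower. The muscle phosphoglycerate mutase Pgam2 was at -1.63, Pkm at -0.92, Hk2 at -0.79 and Tpi1 at -0.72. Fatty acid oxidation genes had a median of 0.02 at percentile 67.0, with 9 of 18 lower. Of these genes 3 were at least 1.5-fold lower and 2 at least 1.5-fold higher, Pdk4 at 2.03 and the acyl-CoA thioesterase Acot1 at 1.04. Differences between lists were not tested. With the local background column subtracted, the oxidative phosphorylation (-0.28) and glycolysis (-0.05) medians lay within the random range.

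Proliferation genes had a median of 0.15, above all random lists, with 13 of 15 higher. The mitotic genes Cdk1, Ccnb2 and Birc5 were at 0.31, 0.31 and 0.27, and Aurka was at -0.91. These genes were dim: the deposited values of Ccnb2 were 3.7 in control and 18.2 in depleted muscle. The authors' processed values gave a median of 0.87, and over genes at or above the median intensity it was 0.02, inside the random range.

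The remaining stress and signalling lists did not stand apart. The p53 target genes had a median of 0.08 at percentile 97.1, with Cdkn1a at 1.91 and Ccng1 at -0.93, and integrated stress response genes a median of 0.06 at percentile 94.0, with Chac1 at 2.11 and Vldlr at 1.24. Heat shock genes were at 0.15 (percentile 94.7; Hspb1 0.86, Cryab -0.67), and BMP and TGF-beta response genes at -0.04 (percentile 10.9; Id1 -0.50, Smad6 -0.35). Circadian clock genes had a median of -0.02 at percentile 30.0, while Arntl, which drives the clock's positive arm, was 3.14-fold higher and Dbp 3.90-fold lower. In the authors' processed values the p53 (0.43) and integrated stress response (0.39) medians lay above the random range and the BMP and TGF-beta median (-0.29) below it. Arntl was at -0.23 and Vldlr at -0.84 with the local background column subtracted. Over all 33 lists, 15 stood apart, 7 lower and 8 higher. If genes varied independently, 1.65 would lie outside the central 95% by chance. Genes of a list can move together between any 2 animals, and lists share members, so 1.65 is no measure of an excess.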

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

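The signal given here lies outside the genes compared above, and its choice was made after the values had been seen. Of 2596 probes with no gene name in the annotation that were above background, 7 were at least 2-fold higher on the array of depleted muscle and 15 at least 2-fold lower. These probes were singled out because they show a difference from control muscle in probes that no comparison used. Among the 18498 named genes, 91 were at least 2-fold higher and 79 at least 2-fold lower, 0.919% together. The unnamed probes were thus not shown to differ more often than named genes. The highest ratios belonged to the probes M300011228 (log2 ratio 2.10) and M400011198 (1.23), and the lowest to M400014631 (-2.69) and M200008976 (-2.42).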

How the results depend on the processing

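The subtraction of the local background column was chosen after the data had been seen, and the others were fixed in advance. No paired analysis was possible because each group held 1 array. Of the 15 lists that stood apart, 12 did so in the same direction under every alternative fixed in advance and 7 also with the local background subtracted: mesenchymal progenitor markers (from -0.72 to -0.25), interstitial collagen and matrix (from -0.48 to -0.14), macrophage (from 0.20 to 0.89), erythroid (from -3.04 to -2.08), muscle atrophy (from 0.72 to 1.35), interferon response (from 0.21 to 0.87) and immediate early genes (from 0.15 to 0.86). Of the 18 other lists, 10 stood apart under no alternative. Of 1250 values of named genes under the alternatives, 12 reversed, all with the local background subtracted, 44 came to lie inside the range of genes of like intensity, 29 came to lie outside it and 1165 stayed inside or outside it as before. Changes of sign among genes inside that range in both settings are not counted as reversals. Signal over background limits the dim genes: the median probe lay 17.1 intensity units above the blanks on the control array and 22.8 on the depleted array.

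Counts of lower and higher genes (79 and 91 in the main setting) were 282 and 363 at 1.5-fold and 17 and 27 at 3-fold, by construction, 360 and 502 with the blank spots subtracted, 38 and 209 with scaling to the median, 410 and 604 in the authors' processed values and 441 and 393 with the local background subtracted, and an offset of 16 gave 163 higher genes. Where no cause is given it was not tested. Muscle stem cell markers lay within the random range with the blank spots subtracted (0.21), scaling to the median (0.12), the authors' processed values (0.21) and over brighter genes (0.12). Over brighter genes proliferation genes did too (0.023). Without members shared with another list, glucocorticoid responsive genes were at -0.23, because all 5 of its members that were at least 2-fold higher are among the 6 shared, and regeneration (-0.30) and p53 target genes (0.084) stood apart. The p53 list (0.084 in the main setting) also stood apart with an offset of 16 (0.20), no background correction (0.11), blank spots subtracted (0.43), the authors' values (0.43), brighter genes (0.42), and at 0.084 with unmatched lists, no filter, both arrays above background or the mean of probes. Integrated stress response genes stood apart with an offset of 16 (0.13), blank spots subtracted (0.38), scaling to the median (0.27), the authors' values (0.39), brighter genes (0.29) and unmatched lists (0.058). Fast fibre genes did so with cyclic loess (-0.59), scaling to the median (-0.17), the authors' values (-0.46) and unmatched lists (-0.12), regeneration genes with blank spots subtracted (-0.34) and the authors' values (-0.31), BMP and TGF-beta response genes in the authors' values (-0.29), heat shock genes with scaling to the median (0.45), local background subtracted (0.49) and unmatched lists (0.15), and complement (-0.18) and slow fibre genes (0.10) with unmatched lists.

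With the local background subtracted, Pdgfra (-0.70), glycolysis (-0.051), oxidative phosphorylation (-0.28), inflammatory (0.026), secreted signal (-0.017) and tenocyte lists (-0.0053) lay within their ranges and the stem cell list was at -0.0087. The named genes that reversed there were Arntl (-0.23), Cldn5 (-0.054), Fos (-0.10), Ifit3 (-0.082), Inmt (0.66), Lyz2 (-2.64), Maff (-0.19), Myoz2 (-3.00), Pvalb (3.50), Slc43a1 (-0.27), Vegfa (0.057) and Vldlr (-0.84). That column follows the spot's own signal, with Spearman correlations of 0.942 and 0.969.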

Other observations

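All tests of explanations here were chosen after the result was seen. Some genes were above background on 1 array only and give bounds. On the depleted array only, the neutrophil chemokine Cxcl2 was at least 1.27-fold higher, Serpinb10 at least 1.19-fold, the myeloid growth factor Csf2 at least 1.14-fold, Neurog2 at least 1.13-fold and the cytokinesis gene Cep55 at least 1.08-fold. On the control array only, Rspo1, a secreted amplifier of Wnt signalling, was at least 1.13-fold higher, the adipokine gene Lep at least 1.06-fold, C1qtnf3 at least 1.05-fold, and Olfr781 and Mogat1 at least 1.04-fold. The offset draws these folds toward 0. In deposited values Cxcl2 was 16.8 in depleted muscle and empty in control, and Csf2 was 6.71-fold higher (1.4 to 9.4). Rspo1 was 9.1 in control and empty in depleted muscle, and Olfr781 was 3.08-fold lower (4.0 to 1.3). The positive control spots were brighter on the depleted array, at mean intensities of 850.6 on the control and 1800 on the depleted array for positive control 2 and of 5668 and 9837 for positive control 3, before normalization.

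Mesenchymal progenitor markers were lower by a median of -0.53. Array background and scaling as the whole cause is argued against, since the highest median over the alternative backgrounds and scalings was -0.25 and each lay below its random range. A lower share of all non-muscle cells would lower endothelial and mural markers alike, but the lower of their lower quartiles was -0.091, above the progenitor median. Less tendon in the sampled piece, as the whole cause, would lower tenocyte markers at least as much. Their lower quartile was -0.33, above the progenitor median, although Kera (-1.41) and Tnmd (-0.98) lay below it. In the authors' processed values that quartile was -0.58 and the progenitor median -0.71. The tenocyte list itself lay below its random range (-0.14, 9 of 12 lower), so a part played by tendon stays open. The loss of the targeted cells, which the design names, stays open as an untested hypothesis, with 1 array per group.

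Muscle atrophy genes were higher by a median of 0.99. Array background and scaling is argued against, since the lowest median over the alternative backgrounds and scalings was 0.97 and each lay above its random range. Denervation that raised acetylcholine receptor and junction genes as a set by about as much is argued against. The upper quartile of that list was 0.13, below the lower quartile of the atrophy genes at 0.59. Of its 17 members 8 were higher, with Gadd45a at 1.41, and 9 were lower, with Chrne at -0.43. The list mixes junction genes with denervation genes, which need not move alike, so it cannot decide on denervation as such. A glucocorticoid response stays open: the 9 responsive genes that are not on the atrophy list had a median of 0.024 (random range from -0.29 to 0.25), with 5 higher and 4 lower. Fasting, illness of the animal and depletion itself were not tested, and any of them may apply, alone or together.

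Among clock genes, Arntl was higher (1.65) and Dbp lower (-1.96). Different clock phases of the 2 animals could give this pattern. By sign alone, 7 of 9 other clock genes went the way such a shift predicts. Nr1d1 was at 1.03 and Per1 at 0.02 (both named after their values were seen), so the test leaves a shift of phase open. Most differences were small: of the 15 measured clock genes, 1 was at least 1.5-fold lower and 2 at least 1.5-fold higher. Array background and scaling stays open for Arntl, whose lowest value over the alternatives was -0.23, with the local background column subtracted. Dbp was below 0 under each of them, from -2.93 to -1.66. A difference between the 2 animals unrelated to depletion cannot be told apart from an effect of depletion for these genes or any other, because there was 1 array per group.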
